A study of Bos taurus with 16 samples.

How the data were processed

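RNA was measured in cumulus cells and granulosa cells of cattle (Bos taurus). Cumulus cells surround the oocyte inside the ovarian follicle, and granulosa cells line the follicle wall. The follicles lay on the ovary that carried the corpus luteum, the progesterone-secreting gland left after ovulation (ipsilateral), or on the opposite ovary (contralateral). Per the design text, each pool held material of 3 animals and 4 pools were made per group, which gave 16 libraries. The labels do not say whether pools of different groups share animals, so no pairing was used and the p values measure the spread between pools.

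Per the labels' protocols, RNA was column-purified with DNase treatment, cDNA was made with the SMART-Seq HT kit and libraries with Nextera XT, and single-end reads of 75 bp were sequenced. These kits do not mark the strand of the RNA. The submitters' processing notes name FastQC, Trimmomatic, STAR and DESeq2 without versions. The genome build, annotation and counting program are not given in the sources used here. The deposited table holds unnormalized read counts per gene, with 36824 genes and 1 column per library, and each column was matched to its sample by the sample's title.

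Total counts lay between 10.1 and 21.9 M per library (M, mega). A count of 0 allows up to 3 counts, which is 0.135 CPM (counts scaled to a library total of 1 M) in the deepest and 0.317 CPM in the shallowest library. Such limits cover counting error only, since reads amplified by PCR are not independent molecules. Replicates were compared before averaging, and their chi-square per gene lay between 12.9 and 78.7, where repeat sequencing of 1 library would give about 1.

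Of the gene entries, 27607 carry an Ensembl ID, 7848 an NCBI LOC number and 1369 a symbol. The Ensembl entries hold 94.4% of all counts. The reference used for names (RefSeq genes of the assembly ARS-UCD2.0) holds no Ensembl IDs, so these entries were tested but could not be named. By NCBI gene number, 1105 LOC entries received a symbol, and 2474 entries have a name in all. Symbols are given as in the count table, with the current symbol in parentheses where it differs. Some genes were counted under more than 1 entry. Among 17227 entries with at least 160 counts, 146 had the same counts as another in every library. Leaving out such exact repeats gave 10817 called genes between the cell types in place of 10858. Of 725 symbol entries compared, 138 lay within 2% or 2 counts of an Ensembl entry in every library, as did 23 of 107 named genes. LOC entries were not compared in this way. These near repeats stayed in the tests, so numbers of genes tested or called are numbers of entries. Of 98 named genes that the reference places, 44 overlap another gene, for example TIMP1 (SYN1), SYN3 (TIMP3) and OST4 (AGBL5). Without strand, the reads of such pairs cannot be assigned with certainty.

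Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), and libraries were scaled with TMM factors. Dispersions were estimated with the robust option, and the quasi-likelihood F-test was applied with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Side comparisons used the 8 libraries of a cell type. The cell types, and the difference of the side effects, were compared in all 16 libraries with 4 group means. Log2 fold changes are given with a standard error (SE), taken as the size of the fold change divided by the square root of F. They are ipsilateral minus contralateral or cumulus minus granulosa, and levels are CPM after TMM scaling over all libraries, as mean ± SD. On counts simulated with the means, depths and dispersions of each comparison, edgeR recovered 61.2% of 2-fold changes between sides in cumulus cells, 44.8% in granulosa cells, 23.9% of 2-fold differences of side effects and 67.2% between cell types. On the simulated cumulus side comparison 3 calls by edgeR were false, and with DESeq2 29 of 168 were. In each simulation 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold, and all others were left unchanged. Recovery at an adjusted p depends on how many genes change, and would be lower where fewer do. Between the real cell types 10858 of 18038 genes were called, so 67.2% does not describe that comparison. The changes were placed only in genes above a minimum mean count, so recovery over all genes tested may be lower. Simulated counts covered only genes kept by the filter and used edgeR's dispersions, whereas DESeq2 was run on the real counts without that filter.

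Before the files were seen, 24 gene lists, 11 lists of cell type markers, the tests, their alternatives and the rule for named genes were fixed. A list was to be tested with camera (preset correlation 0.01) if at least 5 members were tested. None of the 35 lists reached this number, since nearly all their genes were not found by name. Only 10 of 860 listed genes, from 5 lists with 1 to 3 members tested, could be followed. Whether the others sit in the unnamed Ensembl entries could not be checked. A value adjusted over the list alone covers only the followed genes of 1 list, so RPL31 and MUC16, each alone in its list, carry no adjustment there, and all followed genes were therefore also adjusted together, chosen after the data had been seen. After the data had been seen, 11 gene families were therefore put together by symbol and tested in 4 comparisons with camera, with an estimated correlation and with fry, and each family p was adjusted over the 11 families.

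For side comparisons, the rule for named genes takes called genes whose groups do not overlap, up to 10 each way, and fills up with the smallest p values, given as not passing. Between the cell types it takes the 12 largest called differences each way with a mean of at least 10 CPM in the higher cell type, and for the difference of side effects the 5 smallest p values each way. Fixed-list genes that passed were added, and 1 gene that the rule takes in granulosa cells is left out of the text and the plots. Family members, genes named for a single library, genes called by DESeq2 and unnamed IDs were chosen after their values were seen.

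The alternatives were DESeq2's size factors in edgeR, library size alone, no filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, an adjusted p under 0.1, other sets of libraries in the fit, and leaving out each library in turn. Fits without the libraries that stood apart and counts thinned to the smallest total were added after the data had been seen.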

Results

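Bovine follicular cells were profiled by RNA-seq in 16 libraries, with 4 each from ipsilateral cumulus, contralateral cumulus, ipsilateral granulosa and contralateral granulosa cells. Total counts were 13.2 ± 2.54 M in ipsilateral and 17.6 ± 2.20 M in contralateral cumulus libraries (SD, n = 4 each), with an exact permutation p of 0.0571 (two-sided, adjusted p 0.171 over 6 tests). They were 17.5 ± 2.99 M and 16.9 ± 4.71 M in granulosa libraries, with an exact permutation p of 0.771. The smallest p these groups allow is 0.0286. The first principal component, with 60.9% of the variance, separated the cumulus from the granulosa libraries.

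The first comparison asked how cumulus and granulosa cells differ. HYDIN, a component of the ciliary axoneme, stood at 67.2 ± 12.3 CPM in cumulus and 3.78 ± 3.23 CPM in granulosa cells (SD, n = 8 each), a 17.3-fold difference. C11H2orf40 (ECRG4), which encodes a secreted peptide precursor, was 11.4-fold higher in cumulus cells, at 1040 ± 250 against 91.1 ± 71.8 CPM. TIMP1, an inhibitor of matrix metalloproteinases, was 39-fold higher in granulosa cells, at 2010 ± 457 against 52 ± 21.4 CPM. The protease inhibitor gene A2M was 70.8-fold higher in granulosa cells, at 544 ± 147 against 8.28 ± 7.16 CPM, and 134-fold without ipsilateral cumulus library 2.

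By edgeR's quasi-likelihood test, 10858 of 18038 genes differed, 5398 higher in cumulus and 5460 higher in granulosa cells. At least 2-fold differences were seen for 2850 and 2642 of these. Among 813 named genes, 251 were higher in cumulus and 209 in granulosa cells.

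The other named genes highest in cumulus cells were LOC527796 (RSKR, log2 fold change 3.86 ± 0.53 SE), KLHL31 (3.34 ± 0.36), the membrane glycoprotein gene EMB (3.29 ± 0.31), KIAA1024L (3.01 ± 0.90), IL1RAPL2 (2.99 ± 0.44), ADSSL1 (ADSS1, 2.61 ± 0.39) and IQCA1 (2.51 ± 0.38). COLQ, which anchors acetylcholinesterase to the matrix, had 2.62 ± 0.27, and the collagen genes COL25A1 and COL21A1 had 3.28 ± 0.33 and 2.87 ± 0.43. Without ipsilateral granulosa library 2, KIAA1024L had 6.82, and it did not pass with ipsilateral libraries alone (adjusted p = 0.114). LOC527796 had 4.80 without contralateral granulosa library 4. For each of these genes all cumulus libraries lay above all granulosa libraries.

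The other named genes highest in granulosa cells were MUCL3 (log2 fold change -7.86 ± 0.92 SE), LOC786474 (PNPLA3, -6.63 ± 0.71), the lysozyme-like gene LYG1 (-6.43 ± 0.37), FXYD3, a regulator of the sodium pump (-5.83 ± 0.46), and FAM46A (-5.68 ± 0.40). The somatostatin receptor gene SSTR1 (-5.42 ± 0.57), NAT16 (-4.71 ± 0.58), PQLC3 (SLC66A3, -4.33 ± 0.24) and the mechanosensitive channel gene PIEZO2 (-4.26 ± 0.59) followed. Without ipsilateral cumulus library 2, MUCL3 had -9.50 and NAT16 -5.64, and without contralateral cumulus library 4, LOC786474 had -8.01 and PIEZO2 -4.95. MARCH11 had 1838 counts in granulosa and 2 in cumulus libraries, all in contralateral library 3, a depth-scaled ratio of 870 with a 95% counting interval from 241 to 7193. For each of these genes all granulosa libraries lay above all cumulus libraries.

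**Figure D1:**
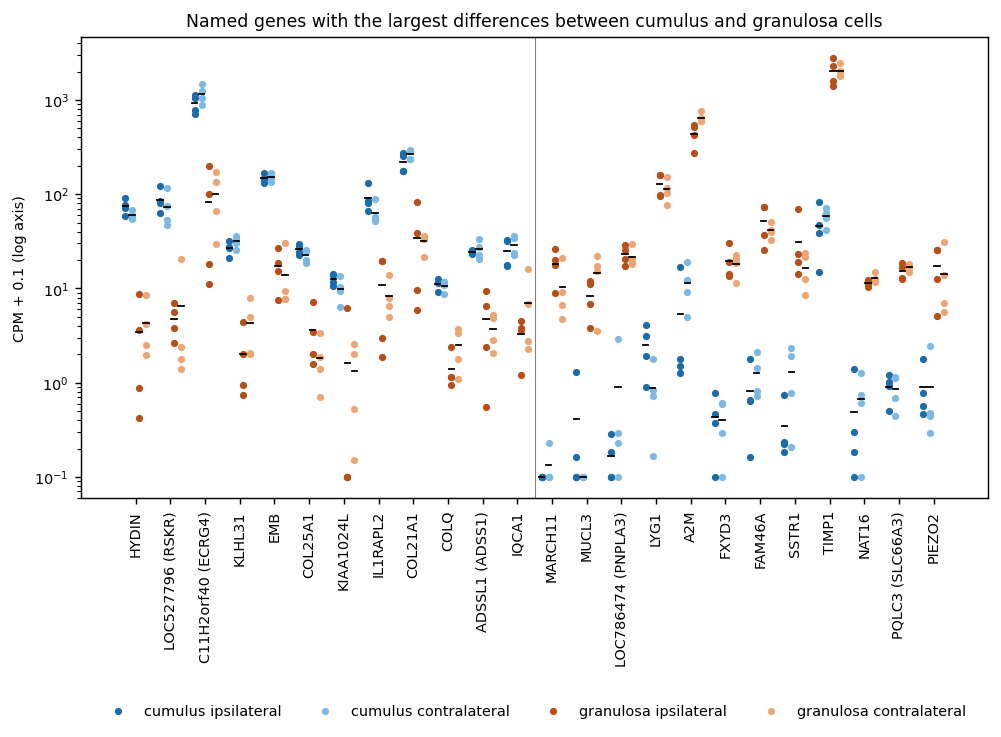
CPM plus 0.1 on a log axis for the named genes with the largest differences between cumulus and granulosa cells; each point is a library, coloured by group (4 libraries each), and each bar is a group mean. TIMP1 had a mean of 2010 CPM in granulosa cells and 52 CPM in cumulus cells.

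Of the 10 fixed-list genes that could be followed, 6 passed over all genes tested. Lower in cumulus cells were the insulin receptor substrate gene IRS1 (log2 fold change -0.82 ± 0.11 SE), CYR61 (CCN1, -0.77 ± 0.13), the laminin gene LAMA5 (-2.35 ± 0.19) and TIMP1. The ribosomal protein gene RPL31 was higher (0.22 ± 0.09), and did not pass by DESeq2 (adjusted p = 0.0709) or without any 1 of 9 libraries (adjusted p from 0.0579 to 0.0951). These were ipsilateral cumulus libraries 1 and 3, contralateral cumulus libraries 1 and 3, ipsilateral granulosa libraries 1 and 4 and contralateral granulosa libraries 1, 2 and 4. LAMA2 (0.41 ± 0.19) passed only when adjusted over the list alone, here 3 matrix genes (adjusted p = 0.0442), and not over the followed genes together (adjusted p = 0.0615). With ipsilateral libraries alone its log2 fold change turned to -0.07. The surface epithelium marker MUC16 was lower in cumulus cells (adjusted p = 0.0294), but ran from 0 to 44.3 CPM among granulosa libraries. It did not pass by limma-voom (adjusted p = 0.283) or without contralateral cumulus libraries 1, 3 and 4, ipsilateral granulosa library 3 and contralateral granulosa library 3 (each left out alone, adjusted p from 0.0505 to 0.164). Its log2 fold change of -7.16 was -10.22 without contralateral cumulus library 2, -6.14 without ipsilateral granulosa library 3 and -4.70 without contralateral granulosa library 3.

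Among families put together after the data had been seen, septins, which form filaments, had 6 of 11 members higher in granulosa cells and 0 higher in cumulus cells. SEPT6 (SEPTIN6) was 6.23-fold, SEPT9 5.32-fold and SEPT2 (SEPTIN2) 1.91-fold higher in granulosa cells. Camera gave an adjusted p of 0.00505, and the adjusted p = 0.0350 with an estimated correlation. Of 19 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 12 were higher in granulosa cells, 3 higher in cumulus cells and 4 did not pass. WARS (WARS1, 2.28-fold), SARS (SARS1, 1.79-fold) and TARS (TARS1, 1.69-fold) were higher in granulosa cells. Camera gave an adjusted p of 0.0297, and the adjusted p = 0.283 with an estimated correlation.

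The other families did not pass with camera. Of 10 collagen genes, 6 were higher in cumulus cells, such as the basement membrane gene COL4A4 (2.38-fold), and 1, COL24A1 (10.6-fold), was higher in granulosa cells (adjusted p = 0.0789). Of 54 zinc-finger genes, 25 were higher in cumulus cells, such as ZSCAN21 (2.34-fold), and 4 in granulosa cells (adjusted p = 0.0789). Of 32 motile cilium genes, 8 were higher in cumulus cells, such as ARMC4 (ODAD2, 4.95-fold), and 5 in granulosa cells, such as TCTE3 (DYNLT2, 12.7-fold, adjusted p = 0.452 for the family). Their median log2 fold change was 0.07, and 0.84 without contralateral cumulus library 4 and contralateral granulosa library 3 (adjusted p = 0.0858 by camera). All 11 RING-CH ubiquitin ligases passed, 5 higher in cumulus cells, such as MARCH6 (MARCHF6, 1.68-fold), and 6 in granulosa cells, such as MARCH3 (MARCHF3, 16.6-fold, adjusted p = 0.407 for the family).

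Of 13 leukocyte genes, 8 were higher in granulosa and 0 in cumulus cells, at low levels such as 1.83 ± 1.29 CPM for the platelet chemokine gene PF4 in granulosa cells (adjusted p = 0.158 for the family). Of 9 germ-cell genes, CAGE1 and TDRD12 were higher in cumulus cells (adjusted p = 0.629 for the family), and TDRD12 did not pass with contralateral libraries alone (adjusted p = 0.0914). Replication-dependent histones had 3 of 18 members higher in cumulus and 4 higher in granulosa cells, such as HIST1H2BB (H2BC15, 3.76-fold, adjusted p = 0.813 for the family). Replacement histones had 4 and 3 of 11, with H2AFZ (H2AZ1) 1.64-fold higher in granulosa cells (adjusted p = 0.913 for the family). Respiratory chain genes had 2 and 3 of 11, with COX18 1.73-fold higher in granulosa cells (adjusted p = 0.813 for the family). Fry, which does not compare with other genes, gave septins an adjusted p of 2.7e-11 and aminoacyl-tRNA synthetases 1.2e-07. It gave collagens 4.8e-08, zinc-finger genes 3.9e-07, RING-CH ubiquitin ligases 2.1e-05, leukocyte genes 1.2e-04 and germ-cell genes 0.0348. The remaining families had 0.109 or more by fry. Since 60.2% of all genes tested were called, these values do not set a family apart.

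The series' title concerns closeness of the follicle to the corpus luteum, and the side comparison in cumulus cells addresses this. None of the following genes passed edgeR's test. SMKR1 stood at 9.53 ± 0.492 CPM in ipsilateral and 20.6 ± 7.04 CPM in contralateral cumulus cells (SD, n = 4 each), with a log2 fold change of -1.11 ± 0.22 SE. CARS (CARS1), the cysteinyl-tRNA synthetase gene, stood at 19.9 ± 1.08 against 38.2 ± 15 CPM, and HSPA6, an inducible heat shock gene, at 4.17 ± 1.80 against 11 ± 4.54 CPM. OST4, a small subunit of the oligosaccharyltransferase, stood at 146 ± 15.4 against 111 ± 4.64 CPM (0.39 ± 0.09).

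By edgeR's quasi-likelihood test, 0 of 16323 genes passed, with a smallest adjusted p of 0.196. At an unadjusted p under 0.05 there were 1791 genes, 685 higher and 1106 lower on the ipsilateral side. DESeq2 called 120 genes, 22 higher and 98 lower. Its named calls were OST4, higher with an adjusted p of 0.0392, and, lower, SMKR1 (0.00358), CARS (0.0207), the oocyte linker histone gene H1FOO (H1-8, 0.0258), MUM1 (PWWP3A, 0.0320), HSPA6 (0.0368) and the oocyte gene BCL2L10 (0.0412). ENSBTAG00000051956 was higher (16.8 ± 1.10 against 3.16 ± 1.93 CPM) and ENSBTAG00000013980 lower (23.2 ± 4.45 against 49.1 ± 7.22 CPM) by DESeq2.

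Contralateral library 4 held BCL2L10 at 112 CPM and H1FOO at 92.6 CPM, and contralateral library 2 held them at 9.64 and 8.96 CPM. Without library 4, DESeq2 called 55 genes, with SMKR1 (adjusted p = 0.0106) and CARS (0.0255) among them, and OST4, MUM1, HSPA6 and BCL2L10 had adjusted p values of 0.166, 0.177, 0.197 and 0.230. Its log2 fold changes with all libraries and without library 4 were 0.39 and 0.38 for OST4, -0.40 and -0.37 for MUM1, and -1.41 and -1.10 for HSPA6. They were -6.02 and -2.94 for BCL2L10, and -6.11 and -3.13 for H1FOO, to which DESeq2 then gave no adjusted p. Without libraries 2 and 4, which leaves 2 contralateral libraries, DESeq2 called 596 genes, 69 of them among the 120, and edgeR called 30.

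The other named genes with the smallest p, none past edgeR's threshold, had lower ipsilateral values for MUM1 (log2 fold change -0.40 ± 0.09 SE), CFAP44 (-1.58 ± 0.43), SYN3 (-0.55 ± 0.16), the kinase gene TNIK (-0.47 ± 0.14), SLC9C2 (-0.37 ± 0.12), TAF7 (-0.37 ± 0.11) and CILP (-2.23 ± 0.73). Ipsilateral values were higher for ATP5MD (ATP5MK, 0.44 ± 0.12) and ATP5MPL (ATP5MJ, 0.36 ± 0.12), small subunits of ATP synthase, MNF1 (0.48 ± 0.13), LOC101906870 (HIRA, 0.75 ± 0.24) and HS3ST4 (2.28 ± 0.73). FAM96B (CIAO2B, 0.28 ± 0.09), FAXDC2 (0.44 ± 0.14), RBM8A, an exon junction gene (0.25 ± 0.08), and TCTEX1D2 (DYNLT2B, 0.52 ± 0.18) followed. The 4.87-fold difference of HS3ST4 was 2.84-fold without ipsilateral library 3, and CILP had a log2 fold change of -1.59 without contralateral library 4 and -3.35 without ipsilateral library 2. The fixed-list gene LAMA5 (-0.94 ± 0.33) passed when adjusted over the list alone, here 3 matrix genes (adjusted p = 0.0443), and not over the followed genes together (adjusted p = 0.133).

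In the respiratory chain family, chosen after the data had been seen, 11 of 11 members had a log2 fold change above 0 in cumulus cells, with a median of 0.24. No member passed over all genes, and 3 passed when adjusted over the list alone. Camera with the preset correlation of 0.01 gave an adjusted p of 4.96e-05. The estimated correlation was 0.52, with which camera gave an adjusted p of 0.440, and fry gave 0.136. Of the 11 genes, 10 were highest in ipsilateral library 3, with a median log2 ratio of 0.48 to the other cumulus libraries. Germ-cell genes had a median of -0.51 over 8 members, with an adjusted p of 0.0459 by camera and an adjusted p = 0.440 with an estimated correlation. Without library 4 their median was -0.51, with an adjusted p of 0.105 by camera. Replication-dependent histones had an adjusted p of 0.131, and without library 4 of 0.00272 (adjusted p = 0.546 with an estimated correlation). The other 8 families had adjusted p values of 0.131 or more by camera.

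The same side comparison was made in granulosa cells, where none of the following genes passed. The zinc-finger gene ZNF175 stood at 18 ± 2.04 CPM in ipsilateral and 27.3 ± 1.22 CPM in contralateral cells (SD, n = 4 each), with a log2 fold change of -0.60 ± 0.15 SE. A2M stood at 440 ± 123 against 648 ± 81.5 CPM (-0.56 ± 0.20). CASC4 (GOLM2), a Golgi membrane gene, stood at 152 ± 18.2 against 113 ± 15.8 CPM (0.43 ± 0.14), and the matrix gene MXRA5 at 16.9 ± 3.77 against 9.02 ± 3.34 CPM (0.90 ± 0.31).

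By edgeR's quasi-likelihood test, 0 of 16411 genes passed, with a smallest adjusted p of 0.770, and 579 had an unadjusted p under 0.05. That count ran from 469 (without contralateral library 2) to 904 (without ipsilateral library 3) when each library was left out. It was 1137 with all 16 libraries in the fit. DESeq2 called 1 gene, ENSBTAG00000021855, at 5.07 ± 0.644 against 14.8 ± 3.26 CPM. Without contralateral library 3, left out after the data had been seen, it called 11, 10 higher and 1 lower on the ipsilateral side.

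The other named genes with the smallest p had lower ipsilateral values for ZNF285 (log2 fold change -2.44 ± 0.64 SE), PRUNE2 (-2.42 ± 0.77), TTC25 (ODAD4, -1.64 ± 0.58), EVA1A (-0.87 ± 0.31), MARCH8 (MARCHF8, -0.42 ± 0.16), the protocadherin gene PCDH9 (-0.82 ± 0.32), C1H21orf58 (-1.59 ± 0.63) and PRR29 (-1.88 ± 0.75). Higher ipsilateral values were seen for FAM122B (PABIR2, 0.80 ± 0.26), the linker histone gene H1FX (1.19 ± 0.40), GULP1 (0.56 ± 0.21) and MARC2 (MTARC2, 0.72 ± 0.29). LAMA2 (0.82 ± 0.33), C10H15orf41 (CDIN1, 0.48 ± 0.21) and FAM173A (ANTKMT, 0.89 ± 0.39) followed. Without contralateral library 3, PRUNE2 had -1.39 and TTC25 -0.91, and ZNF285 had -3.30 without ipsilateral library 4. None of these passed, and no fixed-list gene passed when adjusted over the list alone.

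**Figure D2:**
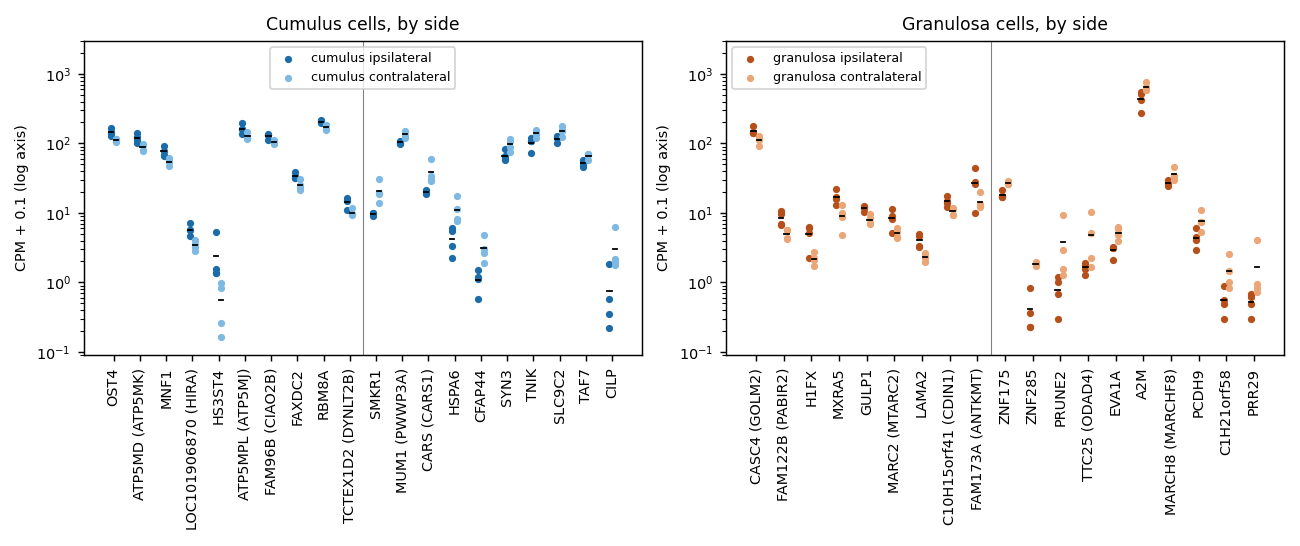
CPM plus 0.1 on a log axis for the named genes with the smallest p in the side comparison, in cumulus and in granulosa cells; each point is a library (4 per side) and each bar is a group mean. Of these genes 0 passed edgeR's test.

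Of the replication-dependent histones, a family chosen after the data had been seen, 13 of 14 had a log2 fold change above 0 in granulosa cells, with a median of 0.63. HIST1H2AC (H2AC6) had 0.65 ± 0.32 SE and HIST1H1D (H1-3) 0.60 ± 0.30, and no member passed. HIST2H2AA4 and HIST1H2AK, counted here as separate members, carried the same log2 fold change of 0.66. Camera gave the family an adjusted p of 1.43e-04, with an adjusted p = 0.113 with an estimated correlation and 0.0532 by fry. Motile cilium genes had 23 of 28 members below 0, with an adjusted p of 0.00111 by camera and an adjusted p = 0.546 with an estimated correlation. Contralateral library 3 held CFAP44 at 32.1 CPM and WDR63 at 19.6 CPM, where the highest of the other granulosa libraries held 1.89 and 1.17 CPM. Without it camera gave the cilium genes an adjusted p of 0.805. The other 9 families had adjusted p values of 0.108 or more by camera. Fry's mixed test, which counts changes either way and does not compare with other genes, gave the zinc-finger genes an adjusted p of 0.0127.

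**Figure D3:**
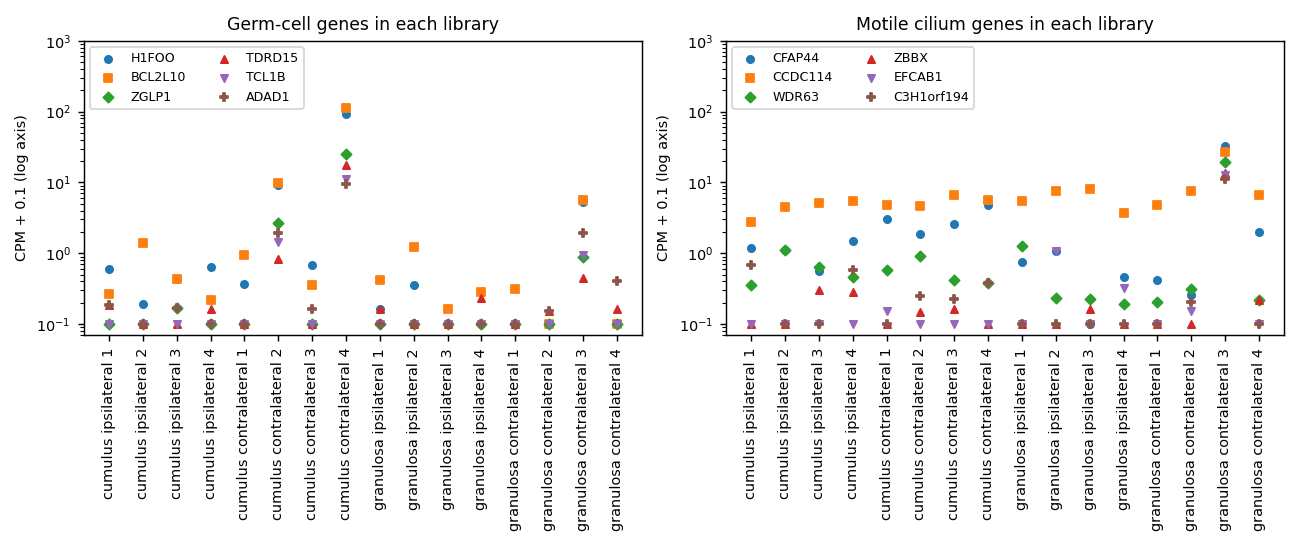
CPM plus 0.1 on a log axis for 6 germ-cell genes and 6 motile cilium genes in each of the 16 libraries, with 1 point per gene and library. BCL2L10 reached 112 CPM in contralateral cumulus library 4, and CFAP44 reached 32.1 CPM in contralateral granulosa library 3.

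The last comparison asked whether the side difference itself differs between cumulus and granulosa cells, and none of the following genes passed. The largest differences by p, cumulus minus granulosa, were MXRA5 (-3.18 ± 0.81 SE), CASC4 (-0.59 ± 0.17), HSPA6 (-1.73 ± 0.52), MUM1 (-0.53 ± 0.16) and SMKR1 (-1.37 ± 0.42). In the other direction stood TTC25 (2.22 ± 0.67), NHEDC1 (SLC9B1, 2.70 ± 0.85), DLGAP2 (1.93 ± 0.61), RBM8A (0.43 ± 0.14) and EVA1A (1.41 ± 0.47). The 4.65-fold value of TTC25 was 2.84-fold without contralateral granulosa library 3, and NHEDC1 had a log2 value of 3.31 without ipsilateral granulosa library 4. MXRA5 had -2.52 without contralateral cumulus library 4 and -3.90 without ipsilateral cumulus library 1. The laminin genes LAMA2 (-0.96 ± 0.38) and LAMA5 (-0.94 ± 0.36) passed when adjusted over the list alone, here 3 matrix genes (adjusted p = 0.0339 for both), and not over the followed genes together (adjusted p = 0.113 for both).

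By edgeR's quasi-likelihood test, 0 of 18038 genes passed, with a smallest adjusted p of 0.653, 1358 had an unadjusted p under 0.05, and DESeq2 called 1. Across these genes, which are not independent replicates, the side differences of the cell types had a Pearson r of 0.0195 (exact permutation p = 0.785, two-sided) and a Spearman rho of -0.00817 (exact permutation p = 0.913). Pearson's r was -0.0862 without contralateral granulosa library 3 and -0.00333 without contralateral cumulus library 2. Motile cilium genes had an adjusted p of 0.00207 and respiratory chain genes of 0.0119 by camera, with an adjusted p = 0.563 for both with an estimated correlation. Without contralateral cumulus library 4 and contralateral granulosa library 3, camera gave them adjusted p values of 0.691 and 0.0692. Their median log2 differences were 0.51 and 0.22 with all libraries, and -0.02 and 0.22 without these. The other 9 families had adjusted p values of 0.158 or more by camera with all libraries, and fry's mixed test gave the zinc-finger genes an adjusted p of 0.00828.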

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

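The tests of germ-cell, leukocyte and motile cilium genes, of deeper libraries, of genes shared with cumulus library 4 and of the share of DESeq2 calls high in 1 library were chosen after their results had been seen at least in part, and the regroupings and the bounds for the thinned counts were set before. A library is listed here where its gap to the nearest library of its group of 4 exceeded Dixon's critical value. Of 392 sets of 4 values, 35 met this, where chance gives about 1 in 20, here 19.6. Where all other values of a group were 0, as for MARCH11, ZNF469 and H1FOO, any value above 0 was listed, whatever its size. The rate of 1 in 20 does not hold for such sets, so 35 and 19.6 cannot be compared directly.

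Contralateral cumulus library 4 held 62 gene entries at 5 CPM or more that lay below 1 CPM in each other cumulus library, and contralateral library 2 was the highest of the others for 53 of them. Some of these entries carried near the same counts, such as IGHM (566), LOC101908235 (567) and ENSBTAG00000048049 (564), so the number of genes was smaller. Deeper sequencing is argued against, since the deeper cumulus libraries held at most 1 such entry. RNA of the oocyte, which cumulus cells enclose, is a candidate explanation, since 13 germ-cell genes at 1 CPM or more in another cumulus library had a median log2 ratio of 2.98 to the other cumulus libraries and 10 were highest there, though this family was put together after the data had been seen (its 16 detected genes had a median of 1.07 in library 2). Of the 13, ADAD1, H1FOO, TCL1B and ZGLP1 reached 1 CPM elsewhere only in contralateral library 2, at 1.85, 8.96, 1.36 and 2.58 CPM. These entered through a library with the same pattern, so they were not an independent choice. RNA of leukocytes stays open, since 8 leukocyte genes detected in another cumulus library had a median log2 ratio of -0.0241 with quartiles from -0.61 to 0.63. This left out 2 leukocyte genes that lay below 1 CPM in the other cumulus libraries. They were IGHM at 32.1 CPM and LRMP at 2.44 CPM in library 4, against at most 0.730 and 0.425 CPM in the others. No group of the design separates this library, so these tests of gene families could not establish a biological explanation.

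Contralateral granulosa library 3 held 105 such entries among granulosa libraries, and had the most genes detected of its group (22108). Some of these entries also carried the same counts, such as EFCAB1 and ENSBTAG00000008693 (254 each), so the number of genes was smaller. Deeper sequencing is argued against, since the deeper granulosa library held 1 such entry. RNA of cells with motile cilia is a candidate explanation, since 30 motile cilium genes detected in another granulosa library, a family also put together afterwards, had a median log2 ratio of 1.63 to the other granulosa libraries and 21 were highest there. RNA of the oocyte could account for a part, since 23 of the entries stood at 5 CPM or more in contralateral cumulus library 4, 17 in library 2 and 0 in the others, but 8 germ-cell genes detected in another granulosa library had a median log2 ratio of 0.55, and H1FOO stood at 5.25 CPM. Of leukocyte genes, 14 detected in another granulosa library had a median log2 ratio of 0.81, with quartiles from -0.26 to 1.54 and 3 highest there. RNA of leukocytes was not tested as an explanation for this library. No group of the design separates this library, so the tests of the other families could not establish a biological explanation.

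DESeq2 called 120 genes by side in cumulus cells. More counts on the contralateral side are argued against as the cause, since 127 genes were called after every cumulus library was thinned to the smallest total. Regrouping by chance stays open, since 4 of 35 splits of the libraries into 4 and 4, the real one included, gave at least as many calls. The others, with 228, 304 and 207 calls, each exchanged contralateral library 2 for 1 ipsilateral library. They keep most of the real grouping, so this count cannot separate a difference by side from chance. Oocyte RNA in library 4 could account for a part, since 13 of the calls stood at least 4-fold higher there than in each other cumulus library. Of the 120 genes, 42 were called without library 4 (55 calls in all). Without libraries 2 and 4, 69 of them were called (596 in all, and 30 by edgeR). DESeq2 was not run without any other single cumulus library, so the calls lost without library 4 cannot be ascribed to oocyte RNA. The position of the follicle relative to the corpus luteum also stays open.

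The real split gave 0 calls by edgeR in each side comparison, so every split gave as many (35 of 35 in cumulus cells, 35 of 35 in granulosa cells and 100 of 100 drawn for the difference of side effects) and this decides nothing. The highest other splits gave 7, 1 and 8 calls. At an unadjusted p under 0.05, 3 of 35 splits of the cumulus libraries gave at least the 1791 genes of the real one (highest other 1983), and 23 of 35 splits of the granulosa libraries at least its 579 (highest other 1552), so regrouping by chance is not excluded. The other cumulus splits, with 1807 and 1983 genes, also exchanged contralateral library 2 for 1 ipsilateral library. With each cumulus library left out in turn, the count ran from 1340 (without contralateral library 4) to 2630 (without contralateral library 2). Between the cell types, 1 of 100 drawn splits, the real one, gave 10858 calls, and the highest other gave 1.

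Among ipsilateral cumulus libraries, library 1 stood apart with FAM96B at 113 CPM and TCTE3 at 15 CPM. Library 2 stood apart with A2M at 16.8 CPM, APOBR at 0.459 CPM and 1 gene found only there. HS3ST4 at 5.25 CPM and P2RY13 at 0.336 CPM stood apart in library 3, and ZNF469 at 0.0609 CPM in library 4, where a count of 0 allows 0.183 CPM, so it cannot be told from 0. Among contralateral cumulus libraries, TCTEX1D2 stood at 11.5 CPM in library 1, MUC16 at 2.09 CPM in library 2 and CILP at 6.07 CPM in library 4. In library 3, MARCH11 stood at 0.130 CPM, which cannot be told from 0 there (limit 0.195 CPM), DLGAP2 at 1.43 CPM, MARCH1 at 1.82 CPM and TDRD12 at 0.713 CPM.

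Among ipsilateral granulosa libraries, CASC4 at 179 CPM and IQCA1 at 1.10 CPM stood apart in library 1. In library 2, EVA1A stood at 2.03 CPM, KIAA1024L at 6.03 CPM, TCTE3 at 34.2 CPM and MARCH3 at 39.6 CPM, and 7 gene entries were found only there. H2AFY2 at 35 CPM and SEPT7 at 298 CPM stood apart in library 3, and library 4 had 21.9 M counts. Among contralateral granulosa libraries, COL21A1 stood at 21.4 CPM in library 1 and IRS1 at 66.2 CPM in library 2. In library 3, PRR29 stood at 3.96 CPM, EMB at 30.2 CPM, H2AFY2 at 77.4 CPM and APOBR at 0.0991 CPM, which cannot be told from 0 there (limit 0.149 CPM).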

How the results depend on the processing

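Fits without libraries 2, 3 or 4 for their transcripts and the thinned counts were chosen after the data had been seen. The 10858 genes called between the cell types became 7319 with ipsilateral and 8048 with contralateral libraries alone, 12002 at an adjusted p under 0.1, and 10582 to 11055 when each library was left out in turn. The balance of directions, 5398 higher in cumulus and 5460 in granulosa cells, depended on the scaling. It was 6041 and 4904 with library size alone, 5735 and 5257 by limma-voom, and 5285 and 5552 with DESeq2's size factors in edgeR. By edgeR the side counts stayed at 0 under each alternative fixed beforehand and without any 1 library, and by limma-voom with all libraries. DESeq2 called 120 genes by side in cumulus cells, 1 in granulosa cells and 1 for the difference of side effects. In cumulus cells it called 55 without contralateral library 4 (42 shared), 596 without libraries 2 and 4 (69 shared) and 127 on thinned counts, and edgeR called 30 without libraries 2 and 4. Without contralateral granulosa library 3, DESeq2 called 11 genes by side in granulosa cells. The correlation of the side differences was -0.00817 as Spearman's rho, and Pearson's r ran from -0.0862 to 0.119 when each library was left out in turn. LAMA2 between the cell types had a log2 fold change of -0.0713 with ipsilateral libraries alone. Among genes named between the cell types, there were 14 losses of a call without 1 library, 9 for RPL31 and 5 for MUC16, and 16 under other settings, 6 and 4 for these genes. The cause was not tested for any of these changes. A level below 0.135 to 0.317 CPM cannot be told from 0 at these depths.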

Other observations

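The comparison of spreads, the test of RN18S1 and the naming of MUC16 by library were chosen after the data had been seen. The spread between pools was larger in granulosa cells. Over 15128 genes tested in both cell types, the median biological coefficient of variation was 0.2 in cumulus and 0.276 in granulosa cells, and it was larger in granulosa cells for 89.1% of genes. These values come from edgeR's dispersions per gene, which are drawn toward the trend of each cell type. The share of genes therefore partly repeats the difference between the trends. MUC16 stood at 44.3 CPM in ipsilateral granulosa library 3, 24.7 CPM in contralateral library 3 and 9.98 CPM in ipsilateral library 1, and at 0.739 CPM or less in the other granulosa libraries.

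RN18S1, a ribosomal RNA gene, stood at 300 ± 56.3 CPM in ipsilateral and 233 ± 10.5 CPM in contralateral cumulus libraries (SD, n = 4 each, exact permutation p = 0.0571, adjusted p 0.171). In granulosa libraries it stood at 405 ± 119 and 319 ± 61.2 CPM (exact permutation p = 0.286).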
